A study of Danio rerio with 3 samples.

How the data were processed

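The series holds single-cell RNA sequencing of zebrafish embryos that carry the olig2:EGFP transgene, which marks the motor neuron progenitor (pMN) domain of the ventral spinal cord and cells that come from it. Per the labels, embryos of 24, 36 and 48 hours post fertilization (hpf) were dissociated, EGFP-positive cells were sorted, and 1 library of the droplet 3' chemistry of 10x Genomics was made per stage. There was 1 library per stage, so no replicate error could be computed and no test between stages was made. All intervals are 95% intervals for counting error only. They are exact Poisson for summed unique molecular identifiers (UMIs) and for numbers of cells in co-detection, and exact Clopper-Pearson for shares of cells.

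Per the submitters' processing notes, Cell Ranger 3.0.1 and Seurat 3.1.0 were used with the genome build GRCz11; the order and settings of the steps were not given. The deposited table holds 18552 genes and 6489 cells, and its values are the natural log of 1 plus UMIs per 10000 of the cell's own total, as the authors computed them. The deposited cell table gives the total count of UMIs and of detected genes per cell, the mitochondrial part as a fraction, and cell cycle scores with the phase call that the authors drew from each score. It also gives the authors' 17 clusters at a resolution of 0.6, without names. The highest mitochondrial part of a cell was 5.00% and the lowest UMI total 502. The log was undone here with each cell's deposited total: all 11593766 values above 0 gave whole UMI counts within a tolerance of 1e-06, and in all 6489 cells they summed to the deposited total. A column of the cell table names the 2390 cells of the 48 hpf library after 36 hpf; the library was therefore taken from the start of the cell name, which another column of the table repeats for every cell. The table has no row for EGFP. Genes are named as in the table, and no positions are given because no genome or annotation was used.

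The authors' clusters served as classes. A cluster took the name of a marker list when at least 3 members of the list had a UMI in 10% or more of its cells, at 1.5-fold or more the level of all other cells, and when that list had more members than any other among its 10 top genes. A cluster that no list named so, and in which at least 50% of both the cycling and the pMN progenitor markers met the share and fold conditions, was called a cycling progenitor. The name was kept only where at least 3 members met those conditions within each library as well, a condition set after the clusters were seen. The glutamatergic interneuron list named cluster 4 and the oligodendrocyte precursor list named cluster 6 over all cells but not in every library, so both kept their numbers, as did clusters 9, 10, 11, 12, 14 and 15, which no list named. Progenitors are clusters 1 and 5, neuronal precursors clusters 2 and 7, and motor neurons clusters 0 and 13. Class names are names for expression patterns, and differences between classes are descriptions.

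For each gene, UMIs were summed over the cells of a library and given as CPM, counts per 1000000 UMIs of that set of cells, over all cells and again within progenitors and within motor neurons. Log2 ratios compare 48 with 24 hpf unless another pair is named. A gene is called higher or lower only as a size: at least 1.5-fold with Poisson intervals that do not overlap. A count of 0 was set to the floor of 3 counts, and such ratios are bounds. A share of 0 said to allow a share up to a limit has a limit of 3 cells of the total, which is not a Clopper-Pearson bound; a share of 0 given with an interval has the Clopper-Pearson interval. List values are the median log2 ratio over members with 30 or more UMIs in both libraries together, for lists with at least 4 such members, minus the median of all genes with that many UMIs. The percentile is the place of the list among 10000 random lists of the same size matched on expression. It describes these libraries and is not a test of stage. Shares of cells with a UMI were also taken after every cell was thinned to 2000 UMIs, with cells below that total left out. Co-detection of a pair of genes is the number of thinned progenitors with both over the number expected from independent detection. Its Poisson interval holds the expected number fixed and ignores that the number with both cannot exceed the number with either gene. The interval is therefore too wide, most of all where a gene is in most cells. Of pairs with an expected number of at least 5, those named here are reported.

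The comparisons, the lists and the genes to be named were fixed before the data were examined. Named in each set of cells are the 12 genes with the highest and the 12 with the lowest ratio among genes with 100 or more UMIs whose 36 hpf CPM lies between those of the other stages. Named per list are up to 4 members with the most UMIs and up to 2 with the largest ratio each way. Named besides are olig2, prdm8, prdm8b, nkx2.2a, sox10, olig1, isl1, isl2a, mnx1, gli1, boc, sox2, her4.1, elavl3 and mki67, and per class up to 5 top genes. The lists cover cell types of the spinal cord, other tissues that a sort could carry over (muscle, blood, myeloid cells, endothelium, epidermis, neural crest and pigment cells, mesenchyme, notochord and cartilage, retina and lens), signalling pathways, the cell cycle, neural tube patterning, Hox groups, forebrain and midbrain genes, the prdm family, dissociation stress and extracellular matrix.

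The size rule was tested on simulated data, with Poisson counts drawn at the depth of each comparison and 200 genes changed. Over all cells, 96.0% of genes raised 2-fold and 90.0% of genes lowered 2-fold were called, 100% of those changed 4-fold either way, and 0.0805% of unchanged genes. In progenitors the shares were 94.0% and 80.0% at 2-fold, 100% at 4-fold both ways, and 0.251% of unchanged genes. In motor neurons they were 88.0% and 76.0% at 2-fold, 100% and 94.0% at 4-fold, and 0.705% of unchanged genes. The simulation held all other genes alike between stages and drew counting error only. In the real libraries the median of all genes shifted and differences between libraries add to counting error. The shares of unchanged genes called therefore do not give a rate of false calls in these data. Alternatives changed the scaling, the UMI minimum, the weight of each cell, the depth, the mix of clusters, the clustering and the members of classes and lists. Scrublet, run per library, marked 17 of 6489 cells (0.262%) as doublets, too few to stand for doublets at this loading, so the comparison without marked cells was replaced, after this was seen, by one without the 5% of cells with the highest scores in each library. Clusterings for the alternatives used 2000 variable genes, 30 components, 15 neighbours and Leiden resolution 1. Tools were python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, scikit-learn 1.9.0, leidenalg 0.10.2 and matplotlib 3.10.9.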

Results

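Gene expression was measured in single EGFP-positive cells sorted from olig2:EGFP zebrafish embryos at 24, 36 and 48 hpf, with 1 library per stage. The libraries held 1952, 2147 and 2390 cells at 24, 36 and 48 hpf, with 16625548, 10977475 and 17146127 UMIs. The median cell had 8670, 4449 and 5766 UMIs and 2012, 1327 and 1940 detected genes. At an equal depth of 2000 UMIs per cell, which left out 240, 292 and 103 cells, the median cell showed 802, 782 and 958 genes. Ribosomal protein genes held 29.2%, 27.1% and 18.7% of UMIs, and mitochondrial genes 0.771%, 1.19% and 2.44%.

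The first comparison asks which kinds of cells made up the sorted population at each stage. Cycling progenitors of the motor neuron domain held 29.8% (27.7 to 31.8) of cells at 24 hpf, 22.2% (20.5 to 24.04) at 36 hpf and 10.6% (9.42 to 11.9) at 48 hpf. Motor neurons went the other way, with 6.35% (5.31 to 7.53), 15.14% (13.6 to 16.7) and 30% (28.2 to 31.9). Neuronal precursors, marked by the Notch ligand gene dld (91.9% against 19.9% of other cells in cluster 2) and by the transcription factor gene olig4 (59.6% against 7.74% in cluster 7), held 13.2%, 17.3% and 14.7%. By cluster these were 9.73%, 10.01% and 7.70% in cluster 2 and 3.43%, 7.31% and 6.99% in cluster 7. Floor plate-like cells held 12.1%, 7.82% and 7.03%, and Kolmer-Agduhr (KA) or V2b interneuron-like cells 5.89%, 1.956% and 5.10%. Mesenchyme-like cells stayed near 1% with 1.02%, 1.21% and 1.38%.

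The progenitor class was marked by gas1b, a hedgehog co-receptor gene, with a UMI in 45.9% against 13.7% of other cells in cluster 1, and by the S phase gene e2f8, with 42.9% against 5.45% in cluster 5. Motor neurons were marked by SYT2, a synaptotagmin gene, with 35.7% against 1.37% in cluster 0, and by glra1, a glycine receptor gene, with 40.1% against 7.09% in cluster 13. The floor plate-like class had the Wnt ligand gene wnt4b in 58.4% against 1.94%, the KA or V2b class had the channel gene pkd2l1 in 50.9% against 0.113%, and the mesenchyme-like class had cthrc1a, a collagen-related gene, in 27.8% against 0.0156%. Genes of lower rank, named after their values were seen, were the choline transporter gene slc5a7a in cluster 0 (66.2% against 4.23%) and shha, the sonic hedgehog gene, in the floor plate-like class (49.8% against 3.65%). Cluster 6 held 7.58%, 4.47% and 8.37% of cells, and its top genes were myrf (27.9% against 0.480% of other cells), vcanb, ugt8, FP017215.1 and p2ry1. These marker shares are over all libraries together, and some hold at later stages only: at 24, 36 and 48 hpf, myrf was in 0%, 0% and 62.0% of cluster 6, glra1 in 0%, 10.8% and 56.2% of the 15, 37 and 105 cells of cluster 13, whose median depths were 1725, 1419 and 6493 UMIs, and cthrc1a in 0%, 38.5% and 36.4% of mesenchyme-like cells. The authors' phase calls put 26.2%, 54.3% and 87.9% of cells in G1, 40.3%, 15.0% and 3.77% in S, and 33.5%, 30.6% and 8.28% in G2 or M. Such calls depend on depth, which differed between the libraries, and on free RNA, which stays open. Within progenitors the S calls were 55.1%, 33.5% and 8.27%, and the G1 calls 2.24%, 5.66% and 53.1%. With classes set by 2 or more markers per thinned cell in place of clusters, a choice made after the data were seen, progenitors held 30.5% at 24 and 4.63% at 48 hpf, and motor neurons 9.35% and 47.4%. A clustering made here with genes scaled within each library, also chosen afterwards, named 0.102% and 2.59% of cells as cycling progenitors, which turns the direction for this class. Of the 4 clusters there that drew most on the authors' progenitor clusters, its naming rule left unnamed those with 386 and 140 cells at 24 hpf and named those with 2 and 0. In that clustering the motor neuron share was 53.7 times and the precursor share 0.0436 times as high at 48 as at 24 hpf, and in one with genes scaled over all cells the floor plate-like share was 0.0907 times as high. Each of these shares holds only the clusters that the naming rule gave that name, and some cells of the authors' floor plate-like class went to clusters of another name.

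**Figure D1:**
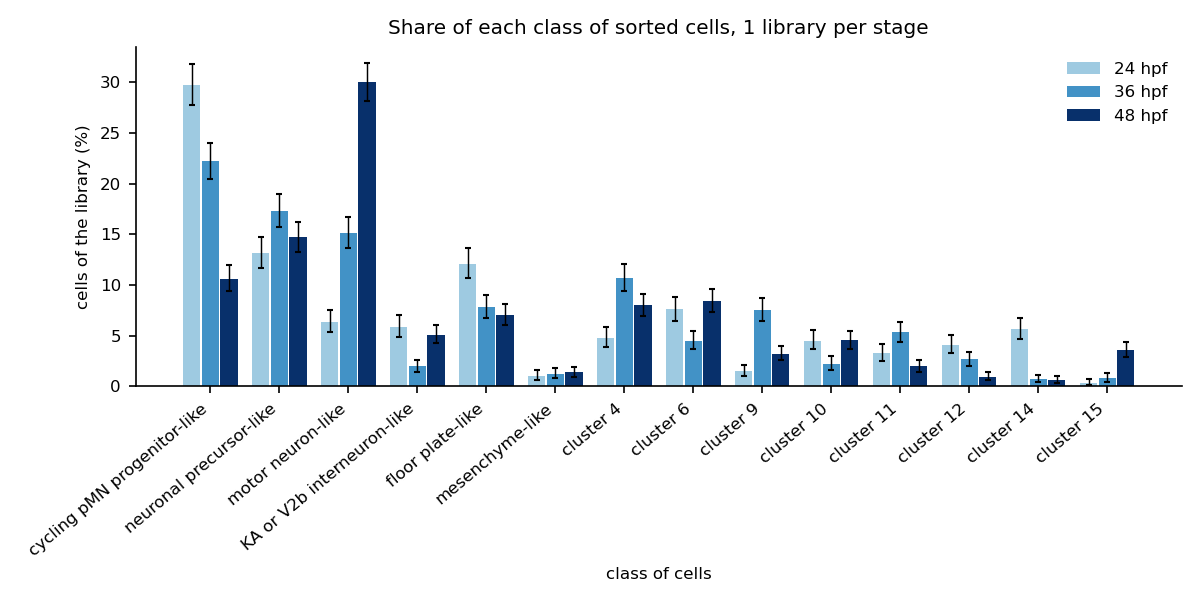
Percent of the cells of each library (vertical axis) in each class or unnamed cluster (horizontal axis) at 24, 36 and 48 hpf, 1 library per stage; bars are shares and lines exact 95% Clopper-Pearson intervals. Progenitors went from 29.8% to 10.6% and motor neurons from 6.35% to 30.0% between 24 and 48 hpf.

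The second comparison asks how expression summed over all sorted cells differed between stages. Neuronal and oligodendrocyte genes were higher at 48 than at 24 hpf, and genes of the cell cycle and of the forebrain and midbrain were lower. The 29 measured pan-neuronal and synaptic genes were each higher by the size rule, with a list median 2.27 above that of all genes on the log2 scale. Of 26 S phase genes, 25 were lower and none was higher, with a list median of -3.49. Of 16 oligodendrocyte lineage genes, 14 were higher and 1 was lower, with a list median of 3.19. It was 1.55 over the 12 members with enough UMIs in thinned cells, and 1.80 over 12 members with a minimum of 300 UMIs at full depth. The median of all genes itself stood at 0.81, with 13985 genes of 30 or more UMIs. Log2 values for all cells are given relative to it, whereas counts of higher and lower genes use the CPM ratio itself. A gene at that median already passes the 1.5-fold condition, so counts of higher genes partly follow this library-wide shift. The share of all genes called higher or lower is not given, so the counts alone do not set a list apart. Among the 11384 genes with 100 or more UMIs, the median was 0.61 with CPM and -0.16 with median-of-ratios scaling. Their ratios spread about it with a median absolute deviation of 1.04 for 48 against 24 hpf. For the steps of equal length it was 0.472 for 36 against 24 hpf and 0.791 for 48 against 36 hpf. The 26 genes named after families of small RNAs, which lack a poly(A) tail, stood together at 1.82 (1.58 to 2.07) relative to all genes over all cells, on 162, 115 and 1033 UMIs. They stood at 2.36 (1.87 to 2.87) in progenitors, on 51, 35 and 112 UMIs, and at 2.51 (1.38 to 3.97) in motor neurons, on 6, 10 and 320 UMIs.

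Among pan-neuronal genes, elavl3, which encodes a neuronal RNA-binding protein, stood at 743, 1376 and 2264 CPM at 24, 36 and 48 hpf, and nefma, a neurofilament gene, at 0.301, 1.64 and 46.3 CPM. The motor neuron list stood at 2.26 (10 higher and 0 lower of 10), with isl1 at 1.83 (1.75 to 1.91), isl2a at 3.28 (3.14 to 3.42), mnx1 at 1.304 (1.21 to 1.403) and isl2b at 1.92, 63.7 and 400.4 CPM. Cholinergic genes stood at 1.43 (5 higher and 0 lower of 5), among them chata, the choline acetyltransferase gene, at 3.37, 7.65 and 187 CPM. Axon guidance and adhesion genes stood at 2.23 (25 higher and 1 lower of 28), with alcama at 48.7, 524 and 1662 CPM, and extracellular matrix genes at 2.24 (16 higher and 0 lower of 18), with hapln1a at 196, 193 and 891 CPM. Glutamatergic interneuron genes stood at 2.41 (5 higher and 2 lower of 8), with sim1a at 1.203, 5.28 and 31.4 CPM. For KA, V2b and other inhibitory interneurons the list stood at 0.02, with 9 higher and 3 lower of 16, and its steps were -1.01 for 36 against 24 and 0.996 for 48 against 36 hpf.

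Oligodendrocyte precursor genes stood at 4.05 (9 higher and 2 lower of 12) and differentiating oligodendrocyte genes at 4.18 (6 higher and 0 lower of 8). The transcription factor gene sox10 stood at 0.361, 7.38 and 130.4 CPM, 7.69 (6.56 to 9.14) relative to all genes, olig1 at 2.66 (2.47 to 2.85) and the myelin gene mbpb at 8.78, 16.5 and 281 CPM. The precursor gene nkx2.9 was lower, -4.29. Radial glia genes stood at 0.67 (7 higher and 3 lower of 11) and neural progenitor genes at 0.44 (7 higher and 4 lower of 12), with fabp7a at 295, 1045 and 2726 CPM and sox19a at 453, 257 and 121 CPM. The pMN progenitor list stood at -0.20 and committed precursors at -0.65, from steps of 0.74 for 36 against 24 and -1.38 for 48 against 36 hpf. The marker gene olig2 stood at 707, 1085 and 1307 CPM, which is 0.08 (0.05 to 0.11) relative to all genes, and prdm8, which encodes a zinc finger regulator, at 113, 168 and 209.7 CPM, 0.08 (0.00 to 0.16). For prdm8b the value was 1.36 (1.05 to 1.69), and for the prdm family 1.25 (8 higher and 0 lower of 10).

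Cycling cell genes stood at -2.74 and G2 and M phase genes at -2.36 (0 higher and 22 lower of 27). The replication gene pcna stood at 1559.9, 825 and 141 CPM and rrm2, a subunit gene of ribonucleotide reductase, at 566, 668 and 3.15 CPM. In contrast mki67 stood at 193, 185 and 158 CPM, -1.09 (-1.17 to -1.02) relative to all genes and neither higher nor lower by the size rule. Forebrain and midbrain genes had the lowest median of the lists with a value, -5.27, with 2 higher and 19 lower of 22 and otx2a at 26.1, 11.5 and 0 CPM, from steps of 0.39 for 36 against 24 and -5.60 for 48 against 36 hpf. Ventral patterning genes stood at -1.01 (5 higher and 6 lower of 14), with dbx1a at 36.8, 19.8 and 1.22 CPM, dorsal patterning genes at -0.69 (3 higher and 2 lower of 8) and floor plate genes at -0.88. Hox groups 1 to 5 stood at -0.01, groups 6 to 9 at 0.43 and groups 10 to 13 at 0.45. Notch genes stood at -0.85 (9 higher and 8 lower of 25), with her4.1 at -2.17 (-2.23 to -2.12), hedgehog genes at -0.76 (4 higher and 0 lower of 14), wnt genes at -1.35 (5 higher and 6 lower of 12), and cholesterol synthesis genes at -0.72 (3 higher and 2 lower of 14). Genes that answer to dissociation stood at -0.91 (10 higher and 5 lower of 25), with fosab at 668, 50.1 and 270.4 CPM; with a minimum of 300 UMIs the list stood at 0.31. Their steps were -1.72 for 36 against 24 and 1.71 for 48 against 36 hpf. Of the lists given so far for 48 against 24 hpf, those of pMN progenitors, committed precursors, inhibitory interneurons, radial glia, floor plate, hedgehog, notch, cholesterol synthesis, ventral and dorsal patterning, Hox groups 1 to 5 and the prdm family lie inside the range of 95% of random lists.

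Of 6344 genes whose 36 hpf level lay between the others, the 12 with the highest ratio included ugt8 at 0.1804, 0.638 and 111 CPM and gal3st1a at 0.0601, 0.0911 and 25.4 CPM, whose enzymes make the myelin lipids galactosylceramide and sulfatide. The calcium pump gene atp2b2 stood at 9.09 (6.61 to 14.40), the bicarbonate transporter gene slc4a4a at 8.50 (6.64 to 11.54) and the secretory gene scg5.1 at 9.04 (6.56 to 14.34). The others were vwde, matn3a, mcamb, si:ch211-286c4.6, with 0, 4 and 13513 UMIs, CR847968.1, zgc:153704 and NC-002333.17, a mitochondrial sequence with 144, 155 and 82302 UMIs. The 12 with the lowest ratio included the forebrain transcription factor genes nkx2.4a (255, 167 and 1 UMIs), otx2a, fezf1 (195, 53 and 0 UMIs) and nr2e1 (71, 33 and 1 UMIs). The others were the meiotic gene msh4 (15.3, 3.73 and 0.0583 CPM), sp5l, a target of Wnt signalling (17.7, 1.64 and 0.175 CPM), crhbp (20.5, 4.74 and 0.292 CPM), s100a1, cldnh, CABZ01021592.1, BX085193.2 and si:ch211-226l4.6. Except for NC-002333.17, these genes had 5 or fewer UMIs at the lower stage, which fixes a direction and a wide range, as for nkx2.4a with -8.85 (-14.16 to -6.36).

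Erythroid, endothelial, neural crest and other genes of tissues that the sort should leave out were also detected. Skeletal muscle genes stood 9.92 above all genes for 36 against 24 hpf and at -7.97 for 48 against 36 hpf, with actc1b at 2.17, 1091 and 9.27 CPM. At 36 hpf 97.8% of the 44543 UMIs of the muscle list lay in 6 cells of cluster 12. Erythroid genes and the heme and globin list both stood at 10.13 for 36 against 24 and -11.60 for 48 against 36 hpf, with hbae3 at 3.61, 909 and 5.54 CPM. At 36 against 24 hpf, endothelial genes stood at 4.17, retina and lens genes at 3.48, and myeloid genes at 0.83. These lists had too few members with enough UMIs for 48 against 24 hpf. Neural crest and pigment genes stood at 3.26 at 36 and -2.90 at 48, both against 24 hpf, with dct at 3.13, 36.8 and 0 CPM and foxd3, a crest transcription factor gene, at 1.44, 18.0 and 137 CPM. At 48 against 24 hpf, epidermal genes stood at 2.07 (7 higher and 1 lower of 10), with krt4 at 24.8, 205 and 283 CPM, mesenchyme genes at 2.17, notochord and cartilage genes at 1.86 and skeletal muscle genes at 1.92. Of these lists, skeletal muscle (percentile 75.9) and notochord and cartilage (96.5) at 48 and myeloid (92.5) at 36, against 24 hpf, lie inside the range of 95% of random lists.

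**Figure D2:**
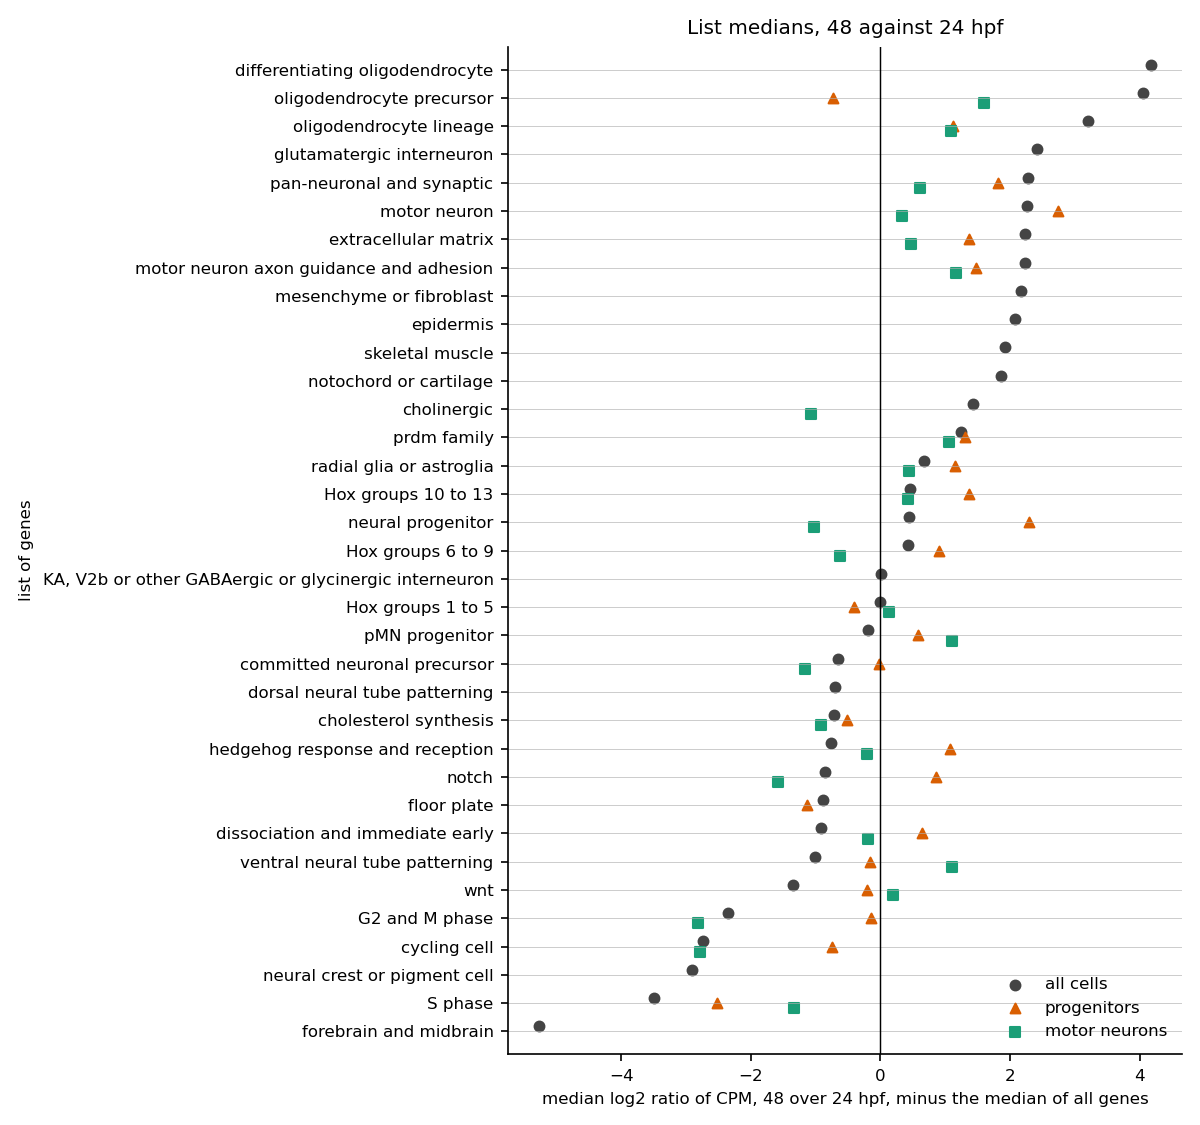
Median log2 ratio of CPM, 48 over 24 hpf, of each list of genes minus the median of all genes (horizontal axis), for the lists on the vertical axis; circles show all cells, triangles progenitors and squares motor neurons, from 1 library per stage. Over all cells the S phase list lies at -3.49 and the pan-neuronal list at 2.27; in progenitors the hedgehog list lies at 1.08 and in motor neurons the notch list at -1.58.

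The third comparison asks how expression summed over progenitors differed between stages. Neural progenitor and hedgehog genes were higher in progenitors at 48 than at 24 hpf, and S phase genes were lower. The neural progenitor list stood at 2.30 relative to all genes, with 9 higher and 0 lower of 12, and the radial glia list at 1.14 (4 higher and 2 lower of 7). Without members that other lists hold the radial glia list stood at -0.0327, so its direction rests on gfap, fabp7a and her4.1. The S phase list stood at -2.52, with 0 higher and 23 lower of 26. Hedgehog genes stood at 1.08 (10 higher and 1 lower of 13) and notch genes at 0.85 (11 higher and 4 lower of 23). The notch list fell first, with -0.29 for 36 against 24 and 0.83 for 48 against 36 hpf. The mix within the class shifted, since cluster 5 held 216 of 581 cells at 24 and 53 of 254 at 48 hpf. Each cluster was also taken alone, relative to its own all-gene median, a choice made after the data were seen. In clusters 1 and 5 the S phase list stood at -3.60 and -1.19 and neural progenitors at 2.48 and 1.85. Hedgehog genes stood at 1.02 and 1.23, notch at 0.85 and 1.07, and radial glia at 1.32 and 0.14. The classes held 581, 477 and 254 cells, the all-gene median was 0.23, and the values below are relative to it.

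The glial filament gene gfap stood at 647, 1155 and 5008 CPM at 24, 36 and 48 hpf, notch3, a Notch receptor gene, at 176, 412 and 1876 CPM, fabp7a at 317, 504 and 2105 CPM and sox2 at 46.5, 34.4 and 308 CPM. The glutamate transporter gene slc1a2b, a marker of astroglia, stood at 1.22, 7.68 and 312 CPM. Among hedgehog genes, hhip, which encodes a hedgehog-binding protein, stood at 43.7, 67.5 and 294 CPM, gli1 at 0.62 (0.09 to 1.14) and boc at 0.78 (0.43 to 1.12), while sufu, a negative regulator, stood at -0.90. Both olig2, at 1.27 (1.21 to 1.32), and prdm8, at 0.92 (0.78 to 1.06), were higher, with 1204, 2264 and 3398 CPM and 188, 358 and 416 CPM. For prdm8b the value was 2 (1.49 to 2.52), and for the prdm family 1.303 (5 higher and 0 lower of 6). The Notch target her4.1 stood at 443, 262 and 594 CPM and nkx2.2a at 24.8, 30.7 and 22.8 CPM, both neither higher nor lower by the size rule.

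G2 and M phase genes went opposite ways in the clusters of the class. Their list stood at -0.15 (7 higher and 5 lower of 27) over the class, but at -0.93 in cluster 1 and 1.27 in cluster 5 alone. Over the class mki67 stood at 269, 399.8 and 730.0 CPM and rrm2 at 902, 1244 and 10.6 CPM. The cycling list stood at -0.75, with -1.40 in cluster 1 and 0.64 in cluster 5. Genes of later stages were detected in progenitors too, with pan-neuronal genes at 1.81 (11 higher and 0 lower of 15), motor neuron genes at 2.73 (4 higher and 0 lower of 5) and axon guidance genes at 1.47. Free RNA as a source of these UMIs was not tested. These motor neuron genes were at low levels, isl1 at 3.86, 20.4 and 30.1 CPM, isl2a at 5.58 (3.64 to 8.68), mnx1 at 1.99 (0.78 to 3.28), and elavl3 stood at 0.87 (0.67 to 1.06). The pMN progenitor list stood at 0.57, the oligodendrocyte precursor list at -0.73 (1 higher and 2 lower of 5), the oligodendrocyte lineage list at 1.12 and olig1 at 1.22 (0.60 to 1.85). For sox10 there were 0, 3 and 8 UMIs, a ratio at least 2.64 above all genes with its 24 hpf count at the floor. Hox groups 6 to 9 stood at 0.90 and groups 10 to 13 at 1.36 (14 higher and 0 lower of 15), with hoxb13a at 0.406, 1.34 and 42.9 CPM, and groups 1 to 5 at -0.40. The matrix list stood at 1.37, wnt at -0.21, cholesterol synthesis at -0.52, ventral patterning at -0.16, floor plate at -1.14 and committed precursors at -0.03. The last 5 of these, the cycling, G2 and M phase, oligodendrocyte precursor and dissociation lists, Hox groups 1 to 5 and the prdm family lie inside the range of 95% of random lists. Dissociation genes were lowest in the 36 hpf progenitors, with 0.64 for 48 against 24 hpf but -2.98 for 36 against 24 and 3.19 for 48 against 36 hpf. Between the same steps the G2 and M phase list changed sign from 0.61 to -0.87, the cycling list from 0.57 to -1.34 and Hox groups 6 to 9 from -0.31 to 0.93.

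Of 2926 eligible genes in progenitors, the 12 with the highest ratio were CR848047.1, CU467822.1 (26, 442 and 8673 UMIs), rpz5 (2, 9 and 577 UMIs), sost (1, 11 and 213 UMIs), CU929451.2, BX465834.1, FO704772.2, slc1a2b, hist1h2a11.4, zgc:165555.14, the TGF-beta receptor gene tgfbr1b (1, 13 and 87 UMIs) and si:ch73-215f7.1. The 12 with the lowest ratio included the chaperone and heat shock genes serpinh1b (197, 8.68 and 2.79 CPM), hspb1 (120, 46 and 1 UMIs) and hsp70.3 (166, 5 and 2 UMIs), and the non-canonical Wnt ligand gene wnt11r (120.3, 10.02 and 6.69 CPM). The others were atic, a gene of purine synthesis (-4.51), gcat, mybbp1a, meis2b (-4.35), oc90, znfl2a, zgc:171242 and si:ch211-226l4.6.

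The fourth comparison asks the same within motor neurons. Genes for axon guidance, adhesion and neuronal function were higher in motor neurons at 48 than at 24 hpf, and more Notch pathway genes were lower than higher. The axon guidance list stood at 1.17 relative to all genes, with 22 higher and 0 lower of 25, and the pan-neuronal list at 0.61, with 21 higher and 1 lower of 29. Clusters 0 and 13 were also taken alone, a choice made after the data were seen. The axon guidance list stood at 1.26 in cluster 0 and 1.11 in cluster 13 (4 higher and 3 lower of 12). The pan-neuronal list stood at 0.55 in cluster 0 and 1.57 in cluster 13 (17 higher and 3 lower of 27). The notch list stood at -1.58, with 5 higher and 10 lower of 18, and committed precursor genes, which went both ways, at -1.16 (3 higher and 5 lower of 12). The classes held 124, 325 and 717 cells and the all-gene median was 0.71. Log2 values over the class, of lists and of single genes, are relative to this median, so a value below 0 can go with a CPM that did not fall. A gene at that median passes the 1.5-fold condition, so counts of higher genes here partly follow the shift of all genes. With each cell weighed alike the notch list stood at -2.70, and with a minimum of 300 UMIs the axon guidance list stood at 2.07.

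The semaphorin co-receptor gene plxna4 stood at 0, 60.9 and 272 CPM at 24, 36 and 48 hpf, cntn2, an axonal adhesion gene, at 3.18, 16.98 and 93.9 CPM, alcama at 197, 1413 and 3022 CPM and slit3 at 196, 284 and 1079 CPM. The neuronal RNA-binding gene elavl4 stood at 750.0, 1302 and 3175 CPM and stmn2b at 1014, 1783 and 363 CPM. For elavl3 the value relative to all genes was -0.41 (-0.47 to -0.34), while its CPM itself rose, by less than 1.5-fold. The motor neuron list stood at 0.32 (6 higher and 2 lower of 10), with 0.29 in cluster 0 and 1.34 in cluster 13 alone. The cholinergic list stood at -1.08 (2 higher and 2 lower of 5), a median inside the range of random lists at percentile 42.3. In clusters 0 and 13 alone it stood at -1.10 and -0.21. Within these lists isl2b (1.06, 432 and 1008 CPM) and chata (56.1, 52.4 and 496 CPM) were higher over the class. The vesicular acetylcholine transporter gene slc18a3a stood at 2325, 1444 and 1112 CPM, isl1 at 0.13 (0.01 to 0.26), isl2a at 0.83 (0.68 to 0.98) and mnx1 at -1.04 (-1.15 to -0.94). The Notch target genes her15.1 (1144, 125 and 60.8 CPM) and her4.3 (79.4, 15.6 and 4.08 CPM) were lower, as were her4.1, at -2.37 (-2.77 to -1.962), and ebf2 (614, 314 and 58.7 CPM), while the receptor gene notch3 was higher (6.36, 38.2 and 45.6 CPM).

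Levels of olig2 in motor neurons were 30.7, 201 and 154 CPM and of prdm8 3.18, 69.4 and 49.1 CPM, with prdm8b at 2.95 (0.42 to 8.27), nkx2.2a at 1.58 (-0.34 to 4.67), olig1 at 3.78 (2.22 to 6.07) and sox2 at 2.84 (0.32 to 8.17). Each of the last 4 had 3 or fewer UMIs at 24 hpf. For sox10 the counts were 0, 0 and 85 UMIs. The prdm family stood at 1.06, pMN progenitor genes at 1.11 (-0.28 with each cell weighed alike), neural progenitor genes at -1.02 (4 higher and 4 lower of 12), oligodendrocyte precursor genes at 1.60, the oligodendrocyte lineage at 1.09 and radial glia genes at 0.44. Cell cycle genes were sparse, S phase at -1.33 (-0.03 in cluster 0 alone), G2 and M phase at -2.81 and cycling genes at -2.79, with pcna at 69.9, 82.8 and 9.82 CPM. For mki67 the value relative to all genes was -0.74, with nearly the same CPM at 24 and 48 hpf. Hox groups 1 to 5 stood at 0.13, 6 to 9 at -0.63 and 10 to 13 at 0.42. Ventral patterning stood at 1.11, hedgehog at -0.21, wnt at 0.19, cholesterol synthesis at -0.92, dissociation at -0.19 and extracellular matrix at 0.47. Inside the range of 95% of random lists lie the neural progenitor, committed precursor, both oligodendrocyte, radial glia, hedgehog, wnt, cholesterol synthesis, dissociation, extracellular matrix and prdm lists and Hox groups 1 to 5 and 6 to 9. The pMN progenitor and ventral patterning lists were highest at 36 hpf, at 2.14 and 2.17 for 36 against 24 and -1.07 and -0.90 for 48 against 36 hpf.

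Of 3500 eligible genes in motor neurons, the 12 with the highest ratio included the transcription factor genes isl2b, nr2f2 (3.18, 140.1 and 949 CPM), meis2a (1.06, 7.08 and 365 CPM), pou2f2a (0, 107 and 519 CPM) and sox12 (1.06, 67.9 and 116 CPM), and nanos1, an RNA regulator gene (1.06, 80.0 and 716 CPM). The others were atp2b2, zgc:158463, CU467822.1, BX548077.1, zgc:165555.12 and NC-002333.17 (10, 23 and 28288 UMIs). The 12 with the lowest ratio included cdx4, a regulator of posterior identity (322, 17.7 and 4.45 CPM), the retinoid metabolism genes rdh10a (319.9, 55.9 and 13.3 CPM) and dhrs3b (125, 29.7 and 5.37 CPM), and ackr3a, a chemokine receptor gene (135, 88.5 and 1.297 CPM). The others were s100a1, cnn3a, proca1, pdgfab, arid3b, si:ch211-56a11.2, her4.3 and her15.1. Many of these ratios rest on few UMIs at 24 hpf, as for isl2b with 9.19 (6.71 to 14.49).

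The last comparison asks in which cells prdm8 was found, beside olig2, genes of oligodendrocyte precursors and hedgehog genes. In progenitors, cells with prdm8 made up 55.8% (51.6 to 59.9) at 24, 72.1% (67.9 to 76.1) at 36 and 77.6% (71.9 to 82.5) at 48 hpf, and 26.7% (22.6 to 31.0), 49.2% (44.2 to 54.3) and 49.8% (43.3 to 56.3) of thinned progenitors. Neuronal precursors had 47.9% (41.6 to 54.2), 65.1% (60.0 to 69.9) and 41.0% (35.8 to 46.4), or 19.1%, 42.1% and 22.1% when thinned. Motor neurons had 2.42% (0.502 to 6.91), 17.2% (13.3 to 21.8) and 21.5% (18.5 to 24.7). In cluster 6 the share was 6.08% (2.82 to 11.2), 13.5% (7.41 to 22.04) and 87.0% (81.5 to 91.3), or 1.399%, 6.74% and 71.9% when thinned. Mesenchyme-like cells, which should lack these genes, had prdm8 in 15% (3.21 to 37.9), 3.85% (0.0973 to 19.6) and 9.09% (1.92 to 24.3) of 20, 26 and 33 cells. Median depths were 9603, 6376 and 6548 UMIs in progenitors, 7940, 4032 and 5080 in precursors, 8864, 4082 and 5048 in motor neurons, 8959, 5216 and 8214 in cluster 6, and 9827, 8076 and 9200 in mesenchyme-like cells. When thinned, motor neurons had 0.935% (0.0237 to 5.10), 9.96% (6.72 to 14.1) and 8.24% (6.32 to 10.5), and mesenchyme-like cells 5.56% (0.141 to 27.3), 0% (0 to 14.8) and 0% (0 to 11.6), whose intervals overlap at each stage.

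A UMI of olig2, the gene whose regulatory sequence drives the sorted label, was in 77.5% (73.8 to 80.8), 87.2% (83.9 to 90.1) and 87.8% (83.1 to 91.6) of progenitors, 69.2%, 84.6% and 81.9% when thinned, and in 15%, 3.85% and 9.09% of mesenchyme-like cells. The cells of cluster 6 at 48 hpf stood apart from those at 24 and 36 hpf: sox10 was in 1.35% (0.164 to 4.80), 4.17% (1.15 to 10.3) and 95% (91.0 to 97.6), nkx2.2a in 46.6%, 43.8% and 96.0%, olig1 in 16.9%, 7.29% and 34.5%, and olig2 in 65.5%, 64.6% and 99.0%. No mesenchyme-like cell had sox10 or olig1, which with 33 cells at 48 hpf allows a share of cells with a UMI of up to 9.09%. Summed levels of prdm8 in cluster 6 were 7.39, 87.2 and 1223 CPM. Floor plate-like cells had nkx2.2a in 70.3%, 83.9% and 88.7%, with prdm8 in 37.3%, 13.1% and 14.9%, at median depths of 8260.5, 4304 and 5354 UMIs.

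Of the hedgehog genes, gli1, a transcription factor gene, was in 12.7%, 11.9% and 15.4% of progenitors and in 0%, 0.308% and 0.418% of motor neurons, and in none of 200 cells of cluster 6 at 48 hpf, which allows a share of up to 1.5%. The co-receptor gene boc was in 23.9%, 20.8% and 38.2% of progenitors and in 0%, 0.615% and 1.67% of motor neurons. The share of 0 for gli1 and boc in 124 motor neurons at 24 hpf allows up to 2.42%. The paralog prdm8b was in 6.71%, 12.2% and 25.2% of progenitors and in 14.8%, 15.05% and 36.8% of neuronal precursors, with none in mesenchyme-like cells.

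Within thinned progenitors, prdm8 and olig2 were found together 0.97 (0.77 to 1.203), 0.99 (0.85 to 1.16) and 1.04 (0.85 to 1.26) times as often as independent detection would give. For prdm8 with boc the value was 0.75, 1.17 and 0.90 at 24, 36 and 48 hpf, with gli1 1.58 and 0.74 at 36 and 48 hpf, with neurog1 1.12, 1.07 and 0.93, and with her4.1 0.90, 0.92 and 0.98. Every reported pair with an expected number of 5 or more in thinned progenitors had an interval that includes 1. These intervals are too wide, so this does not show that detection was independent. Of thinned progenitors with gli1, 14 of 18 had prdm8 at 36 hpf, against 195 of all 396, and 7 of 19 at 48 hpf, against 121 of all 243. Over all neural cells, prdm8 and olig2 were found together 1.198 (1.00 to 1.42), 1.63 (1.45 to 1.82) and 2.099 (1.88 to 2.34) times as often, and prdm8 and sox10 at 48 hpf 3.23 (2.66 to 3.89) times. Other pairs lay below 1: prdm8 with mnx1 at 0.13 (0.02 to 0.46), 0.55 (0.39 to 0.76) and 0.42 (0.31 to 0.56), and prdm8 with isl1 at 0.40 (0.20 to 0.71), 0.92 (0.76 to 1.09) and 0.64 (0.53 to 0.76). The pair of prdm8 with nkx2.2a lay at 0.33 (0.15 to 0.64) at 24 and 0.31 (0.18 to 0.49) at 36 hpf and at 1.59 (1.34 to 1.88) at 48 hpf. Within progenitors at their own depth at 24 hpf, prdm8 lay at 0.49 (0.27 to 0.81) with nkx2.2a, 1.25 (1.08 to 1.43) with neurog1, 1.15 (1.01 to 1.29) with her4.1 and 1.24 (1.02 to 1.51) with sox2. These are the pairs of prdm8 there whose interval leaves out 1, and differences in depth between cells alone raise such values. When thinned, sox2 lay at 0.75 (0.32 to 1.48), her4.1 at 0.90 (0.67 to 1.18) and neurog1 at 1.12 (0.81 to 1.51). For nkx2.2a the expected number was then 4.80, below the minimum of 5.

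**Figure D3:**
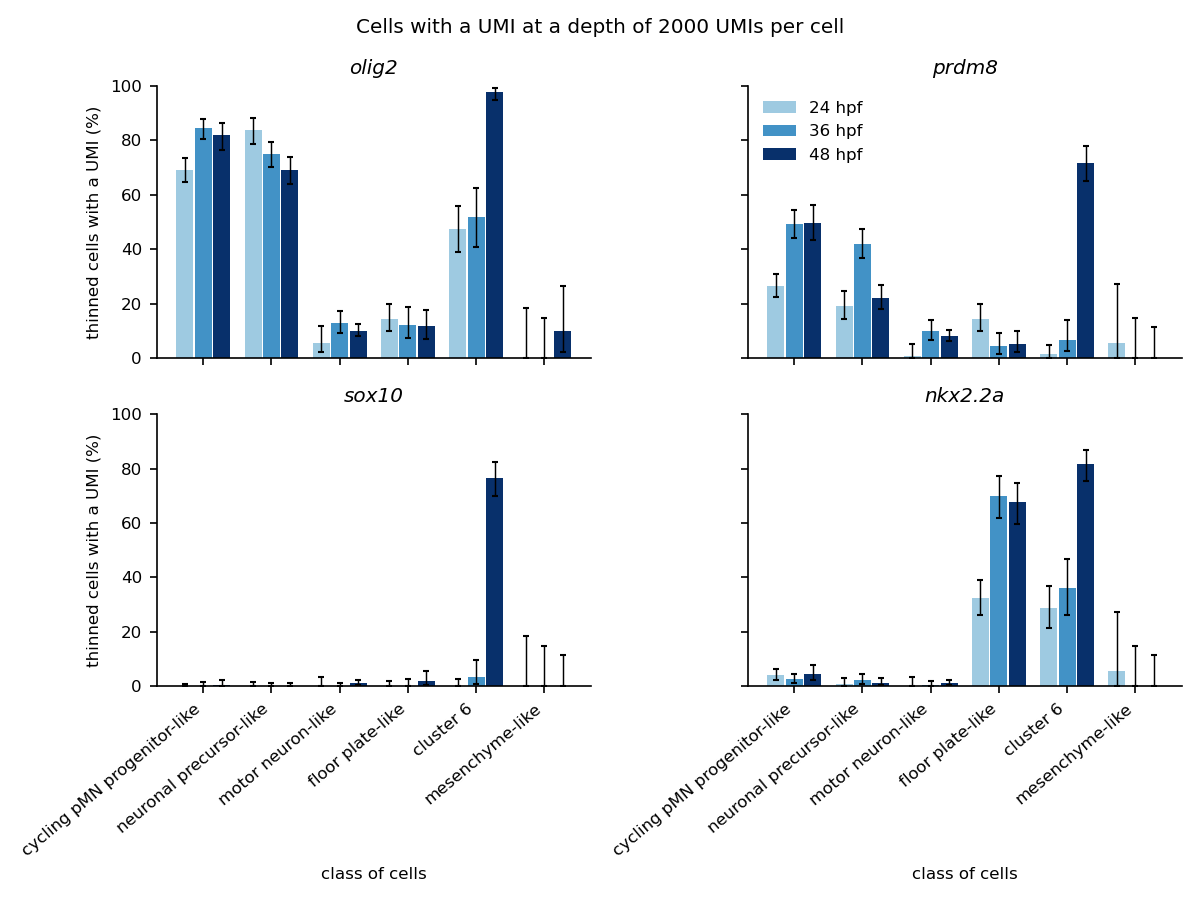
Percent of cells with a UMI of olig2, prdm8, sox10 or nkx2.2a (vertical axis) in each class (horizontal axis) after thinning every cell to 2000 UMIs, at 24, 36 and 48 hpf with 1 library per stage; lines are exact 95% Clopper-Pearson intervals. In cluster 6 prdm8 was in 1.399% of thinned cells at 24 and 71.9% at 48 hpf, and in progenitors in 26.7% and 49.8%.

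The position of cells along the body axis differed between libraries. A UMI of the 24 measured forebrain and midbrain genes was in 15.0% (13.4 to 16.8) of thinned cells at 24, 17.5% (15.8 to 19.3) at 36 and 1.97% (1.44 to 2.62) at 48 hpf, and a UMI of any Hox gene, which marks hindbrain and spinal cord, in 85.3%, 83.1% and 98.3%. In cluster 6 the brain shares were 74.8%, 67.4% and 1.04% and the Hox shares 15.4%, 28.1% and 86.5%. In cluster 4 they were 72.4%, 55.2% and 8.11%, and 26.4%, 42.4% and 100%. Progenitors had a Hox UMI in 94.7%, 96.2% and 100%, and motor neurons in 100%, 100% and 99.9%.

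**Figure D4:**
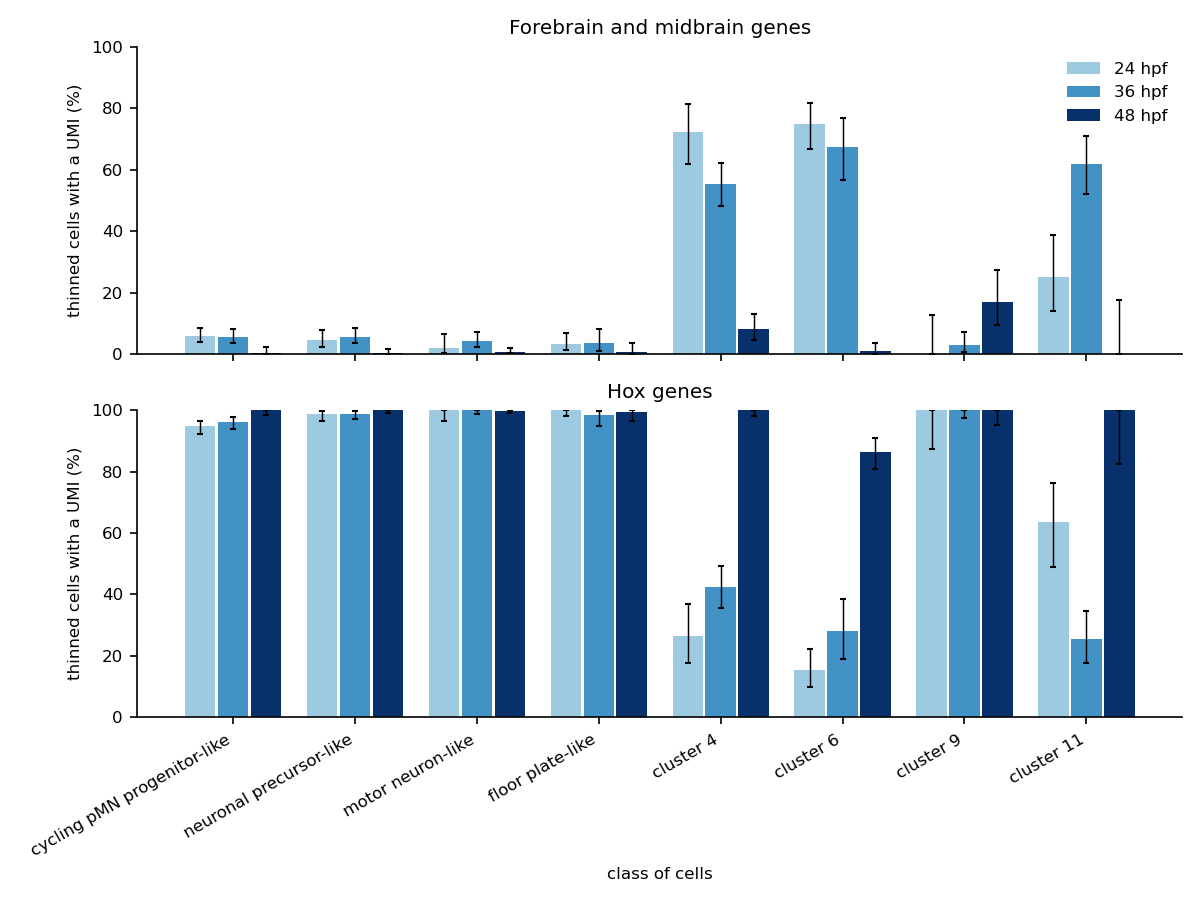
Percent of thinned cells with a UMI of the forebrain and midbrain list (top) and of any Hox gene (bottom) by class (horizontal axis) at 24, 36 and 48 hpf, 1 library per stage; lines are exact 95% Clopper-Pearson intervals. In cluster 6, brain genes were in 74.8% of cells at 24 and 1.04% at 48 hpf.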

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

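Of the tests below, those on the mix of clusters, on depth per cell, on muscle UMIs outside cluster 12 and on the level of the brain list were chosen only after the result was seen.

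The table of all genes and the deposited cell totals did not use every UMI. A further column of the cell table gives totals of an earlier state of the data, which exceed the totals used here by 2216, 2840 and 6136 UMIs at 24, 36 and 48 hpf, a signal in data that the comparisons do not use. The excess lies in 3108 cells (47.9%), and 9 cells with 100 or more hold 3315 of the 11192 UMIs.

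The neural progenitor list had a median of 2.30 in progenitors relative to all genes, with 9 higher and 0 lower of 12, and of -1.02 in motor neurons, where 4 were higher and 4 lower of 12, a difference of 3.32 between the classes. The notch list had medians of 0.85 in progenitors and -1.58 in motor neurons, a difference of 2.43. The oligodendrocyte precursor list, with 5 members each, had -0.73 in progenitors and 1.60 in motor neurons, a difference of -2.33. Each was picked because the medians lie on opposite sides of the median of all genes, and the difference was not tested.

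The 48 hpf library stood apart from the others, with a median absolute deviation of log2 ratios of 1.04 against 24 hpf where 36 hpf had 0.472. The gap in time is longer for the first value. Over a step as long as that from 24 to 36 hpf, 48 against 36 hpf, it was 0.791. Reweighting every library to the same mix of clusters left 0.857 against 0.381, which argues against the shares of the clusters as the whole cause. Some clusters held different cells in different libraries, as their brain and Hox shares show. Equal cluster shares therefore do not give equal kinds of cells, and a different mix of cells within clusters stays open. Thinning every cell to 2000 UMIs left 0.879 against 0.435, over 7383 genes where the values at full depth cover 11384. Thinning changes the CPM of summed cells only through the weight of each cell, the cells left out and counting error. It therefore cannot decide whether depth per cell was a cause, which stays open. Genes of RNA without a poly(A) tail stood at 1.82 over all cells, 2.36 in progenitors and 2.51 (1.38 to 3.97) in motor neurons relative to all genes, the last on 6 UMIs at 24 hpf. Of their 1033 UMIs at 48 hpf, RF00004.10, RF00002.2 and RF00017 held 325, 184 and 161, so the value rests largely on few genes. A difference in capture at 48 hpf would give such values. The stage itself and any difference in preparation or annotation that follows the library were not tested, and with 1 library per stage they cannot be separated from it.

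Muscle RNA at 36 hpf may come from muscle cells, since 97.8% of its UMIs were in cells with more than 10 of them, 6 cells of cluster 12 with 11748 to 45863 UMIs each; the sort should remove such cells. In the other clusters no cell had more than 6 muscle UMIs, and the part of muscle UMIs in cells with more than 10 was 0%, which argues against muscle cells there. Free RNA could be the source in those clusters, where 35.6% of cells had a muscle UMI and 95.1% of these UMIs lay in cells with 1 to 3. The part taken by actc1b ranged 1.66-fold, from 24.1% of 58 muscle UMIs in cluster 9 to 40% of 65 in floor plate-like cells. Such small numbers leave open whether free RNA was the source. No biological explanation was tested.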

How the results depend on the processing

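Over all alternatives and results together, 24 class shares, 330 values of single genes, 34 shares of cells with a gene and 53 co-detection values stayed within the counting interval of the value reported, and 8, 178, 35 and 11 moved beyond it; 1 class share reversed. Signs of list medians stayed for 78 of 83 lists with each cell weighed alike, 77 of 83 with a minimum of 10 UMIs, 56 of 63 with 300, 64 of 68 in thinned cells, 65 of 67 without shared members, 21 of 22 in cluster 1 and 17 of 22 in cluster 5 alone, and 21 of 21 in cluster 0 and 14 of 16 in cluster 13 alone. Median-of-ratios scaling and CPM without ribosomal, mitochondrial and globin genes shift every gene of a library alike, so relative medians cannot move with them. Of the 445 list medians under the other settings, 213 stayed within the counting interval, 32 changed sign, and 3 of these were of lists whose reported median lies outside the range of random lists; these 3 are called reversed below. The alternatives chosen after seeing the data were the clustering with genes scaled within each library, classes from 2 or more markers, cluster 2 among progenitors, cluster 15 among motor neurons, each cluster of a class alone, and leaving out the cells with the highest doublet scores. The cause was not tested for the values below unless one is named.

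With genes scaled within each library, the ratio of shares, 48 over 24 hpf, was 25.3 for cycling progenitors, a reversal where progenitor clusters with 386 and 140 cells at 24 hpf were left unnamed, 53.7 for motor neurons and 0.0436 for neuronal precursors. With 2 or more markers it was 0.152 for progenitors, 0.897 for precursors and 0.886 for floor plate-like cells, and with cluster 2 among progenitors 0.464 for those. The clustering with genes scaled over all cells gave 0.0907 for floor plate-like cells, other cells of that class having gone to clusters of another name, and 0.387 for the clusters that the oligodendrocyte precursor list named, whose cells at 24 hpf came mostly from the authors' clusters 1 and 3. It gave no ratio for progenitors and motor neurons, whose 59 and 930 cells were all from 48 hpf, nor for precursors, which had none there. With genes scaled within each library the cluster that the oligodendrocyte precursor list named had no cell at 24 hpf, while cells of the authors' cluster 6 lay in an unnamed cluster with 222 cells at 24 hpf. Of the 28 clusters with genes scaled over all cells, 10 drew 95% or more of their cells from 1 library, 9 of these from 48 hpf with 80.8% of its cells; with genes scaled within each library it was 5 of 24, 4 of them from 48 hpf with 45.1%.

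Of the 24 genes chosen by ratio, those shared over all cells were 15 with each cell weighed alike, 7 in thinned cells and 13 with the same cluster mix. In progenitors 12 were shared with a minimum of 300 UMIs and 8 in thinned cells, and in motor neurons 15 with a minimum of 10 and 12 in thinned cells.

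Over all cells the S phase median was -3.89 with each cell weighed alike, -3.63 in thinned cells, -3.64 and -3.11 with minimums of 10 and 300 UMIs, and -3.39 without shared members. In the same order, without the last, the pan-neuronal median was 1.82, 2.09, 2.13 and 2.66. The oligodendrocyte lineage median was 2.06 with each cell weighed alike, 1.55 over 12 members in thinned cells and 1.80 over 12 members with a minimum of 300. The dissociation median reversed to 0.31 with a minimum of 300. In progenitors the hedgehog median was 0.70 with each cell weighed alike and 1.48 in thinned cells, the S phase median -2.67 and -2.34 with minimums of 10 and 300 and -2.35 without shared members, and -3.60 and -1.19 in clusters 1 and 5 alone. The notch median was 1.07 in cluster 5 alone, and the radial glia median reversed to -0.0327 without shared members. In motor neurons the notch median was -2.70 with each cell weighed alike, -2.02 in thinned cells, -1.14 with a minimum of 10 -2.53 without shared members, and -1.39 and -2.60 in clusters 0 and 13 alone. The pan-neuronal median there was 0.83 and 1.00 with minimums of 10 and 300 and 1.57 in cluster 13 alone, the axon guidance median 2.07 with 300, and the pMN progenitor median reversed to -0.28 with each cell weighed alike.

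Progenitors with 2 or more UMIs of prdm8 were 36.8%, 52.6% and 59.1%, and thinned ones with any 26.7%, 49.2% and 49.8%, where fewer UMIs alone lower a share. With cluster 2 among progenitors the share was 67.6% at 48 hpf. For olig2 it was 67.3%, 80.5% and 83.1% with 2 or more UMIs, 69.2% and 81.9% at 24 and 48 hpf when thinned, and 90.2% at 36 hpf with cluster 2. For prdm8 in cluster 6 it was 0.676% and 6.25% at 24 and 36 hpf with 2 or more UMIs, and 1.399%, 6.74% and 71.9% when thinned. The co-detection of prdm8 with olig2 over all neural cells was 1.63 at 36 and 2.099 at 48 hpf. For 8 gene values a count of 0 gave no bound. Depth limits genes with few UMIs at 24 hpf in motor neurons, where 124 cells leave many at 3 or fewer.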

Other observations

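The test on the level of the brain list was chosen only after the result was seen.

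Several of the authors' clusters, which no list named in every library, carried genes of neurons, neural crest, retina and tail bud, most of them not in every library. Shares of cells with a UMI are given at 24, 36 and 48 hpf. Cluster 9 carried the hindbrain motor neuron genes phox2a (89.7%, 96.3% and 96.1%), phox2bb (96.6%, 97.52% and 98.7%) and tbx2b (10.3%, 65.2% and 77.9%), and held 1.49%, 7.499% and 3.22% of cells. Cluster 4 had sim1a in 4.301%, 15.3% and 72.3%, uncx in 21.5%, 35.4% and 82.2% and the vesicular glutamate transporter gene slc17a6b in 3.23%, 15.7% and 69.1%, mostly at 48 hpf, whereas at 24 hpf 5 markers of inhibitory interneurons and 1 of glutamatergic interneurons met the marker conditions, and it held 4.76%, 10.7% and 7.99%. Cluster 15 had hs3st1l2 in 42.9%, 11.8% and 62.4% and foxp1b in 0%, 0% and 56.5% of 7, 17 and 85 cells, and held 0.359%, 0.792% and 3.56%. Over all libraries together, 6 of 10 motor neuron markers met the marker conditions in cluster 15, isl1, isl2a, isl2b, chata, slc18a3a and slc5a7a. None was among its top genes, so the list did not name it. Clusters 0, 13 and 15 together held 6.71%, 15.9% and 33.6% of cells.

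Cluster 10 had the neural crest genes snai1b in 0%, 10.4% and 54.6% and foxd3 in 0%, 22.9% and 92.6%, and mcamb in 0%, 14.6% and 90.7%, none of them at 24 hpf, where 5 floor plate markers and all 12 cycling markers met the conditions, and it held 4.51%, 2.24% and 4.52%. Cluster 11 had the retinal genes six6b in 7.81%, 47.4% and 0% and atoh7 in 6.25%, 67.5% and 0% and the forebrain gene foxg1b in 4.69%, 61.4% and 0%, mostly at 36 hpf, and held 3.28%, 5.31% and 1.97%. Cluster 14 carried genes of the early tail bud, eve1 (30.9%, 26.7% and 46.7%) and pou5f3 (80.9%, 53.3% and 40%), and held 5.64%, 0.699% and 0.628%. Cluster 12, with cxcl12b (55.0%, 1.75% and 4.55%), hspb1 (38.8%, 10.5% and 13.6%) and sod2 (51.2%, 8.77% and 31.8%), held 4.098%, 2.65% and 0.921%. These shares are not at equal depth. Median depths were 8838, 3488 and 12026 UMIs in cluster 10, 6812, 7130.5 and 1751 in cluster 11, 12948, 908 and 13732 in cluster 12 and 11597, 6042 and 4255 in cluster 14. The genes phox2bb and pou5f3 were picked after their values were seen.

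Forebrain and midbrain genes were nearly missing at 48 hpf, with a list median of -5.27 relative to all genes where random lists matched on expression gave -0.57 to 1.4996. Genes of like level thus did not fall alike. This test uses the low median that is itself the pattern, so it cannot decide on weaker detection of these genes. At 24 hpf thinned cells with both a brain and a Hox UMI were 0.324 (0.253 to 0.409) times as frequent as independence would give. Cells with forebrain or midbrain genes and cells with Hox genes are thus largely different cells. Fewer forebrain and midbrain cells in the 48 hpf library would give these values. Cluster 9, with hindbrain motor neuron genes, held 1.49%, 7.499% and 3.22% of cells at 24, 36 and 48 hpf. It was thus present at 48 hpf, but its share fell from 36 to 48 hpf, the step in which the brain list fell. Whether the hindbrain was spared stays open. A difference between embryos of these stages in where olig2:EGFP is on was not tested.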
